A study of Homo sapiens with 3 samples.

How the data were processed

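RNA from Hut78 clones was hybridised to 3 Agilent arrays with 2 colours (design 014850), each with 1 SATB1 clone in red and 1 distinct empty-vector clone in green. The replicates are separate clones per the labels. Spot and background brightness is given as intensity per the file headers, the median over the pixels of a spot, made by the authors with Agilent Feature Extraction (10.5.1.1 in the headers, 8.5.1.1 in the submitters' notes). The deposited value table holds the log10 ratio of red over green after the scanner software's background subtraction and dye normalization. It equals the log10 ratio column of the scanner files (largest difference 0), with a median of 0 on each array. The flags for background, saturation and outlying spots are 0 or 1 per the file headers. One description label names the empty vector, replicate 1, on all 3 samples, at odds with their titles and dye labels; the titles and dye labels were used, and the ratio of SATB1 was higher in red on all 3 arrays.

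Median foreground and median background intensity were corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3. The plan named mean foreground signals, which the files do not hold. Spots of a probe were averaged, spots with an outlier mark were left out on that array, and control spots had no weight. A probe was kept when it was well above background in red on all 3 arrays or in green on all 3. The files hold accessions and no gene names, so symbols came from a RefSeq table (GRCh38.p14) through the accession: 23434 of 24863 RefSeq probes matched, and other probes kept their identifier. The headers name build hg17, and the table gave names and the order of genes only. Of a gene's probes, the brightest on average represented it. This left 20144 genes and unnamed transcripts, 11515 of them with a symbol.

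Log2 ratios were tested against 0 with limma (lmFit, eBayes, two-sided) and adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Gene lists with at least 5 measured members (28 of 30) were tested with camera at a preset correlation of 0.01, with the estimated correlation and with fry. With the estimated correlation 0 lists passed and 2 had an unadjusted p under 0.05; fry, which tests the genes of a list by themselves, passed 5 lists for direction (MHC class II, ribosomal, Th1, checkpoint and interferon, all upward) and 26 for change either way. For genes not above background in one group the ratio is the fitted one and no bound.

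The named genes followed a rule: SATB1 and FASLG; among genes with a symbol, an adjusted p under 0.05, the same sign on all arrays and signal above background in the brighter channel on all arrays, the 12 with the largest and the 12 with the smallest ratio; and for each list the 3 members with the smallest p. Some genes that the rule names are not reported here. Genes outside it are said to have been named for a test or after their values were seen. The groups, main tests, lists, rule and alternatives were fixed before the data were examined. Some tests of other explanations were chosen after the results were seen and are marked as such below. The alternatives were other background corrections, the scanner software's processed signals, the deposited table, median centring, no normalization, other filters and probe rules, a trended and robust fit, no replicate block, other thresholds and leaving out each replicate.

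The pairing of clones by number was checked on the deviation of each clone from its group mean: r across genes was 0.51, 0.36 and 0.55 for clones with the same number and between -0.50 and 0.27 for others. Clones with the same number were hybridised together, so that this also carries what the array adds. The test was tried on simulated data with 20144 genes and 200 true changes: 10% were recovered at 1.5-fold, 60% at 2-fold, 96% at 4-fold and 100% at 8-fold, with 7 false among 140 calls, and the list test called the 1 raised list and 0 of the others. The simulated genes were independent, and every member of the raised list was raised 2-fold. These shares therefore do not carry over to data with more changes, or to lists with smaller shifts or correlated genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.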

Results

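Gene expression was measured in Hut78, a human T cell line from a cutaneous T cell lymphoma (Sezary syndrome), after transduction with SATB1, a nuclear protein that organises chromatin. Each of 3 arrays with 2 colours set 1 SATB1 clone (clones 2, 11 and 28 for replicates 1, 2 and 3) against its own clone carrying the empty vector (MIG, a retroviral vector with a GFP marker). The SATB1 clone carried the red dye (Cy5) and the empty-vector clone the green dye (Cy3) on all 3 arrays, so that dye and group were not separated. Each array held 45015 spots and 41000 probes that were not controls. Between 62.8% and 64.6% of these probes were well above background in red and between 63.3% and 64.5% in green, and 0 spots were saturated. The number of arrays limits the precision. All values below are log2 ratios of the SATB1 clone over the empty-vector clone, given as the mean of the 3 arrays with the SD (n = 3), unless another measure is named.

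The comparison asked which transcripts differ between Hut78 clones with and without added SATB1. SATB1 itself, the transduced gene, was 88.4-fold higher in the SATB1 clones, at a log2 ratio of 6.47 ± 0.32 (SD, n = 3). The ratio was 6.25 in clone 2, 6.31 in clone 11 and 6.83 in clone 28. SATB1 was also above background in the empty-vector clones on all 3 arrays. The limma test gave an adjusted p = 0.000924. The exact two-sided sign-flip test gave p = 0.25, the smallest that 3 arrays allow. The labels do not say whether the probe lies in the part of the gene that the vector carried.

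Apart from SATB1, the named genes with the largest increases included LHX2, a LIM homeobox transcription factor (5.10 ± 0.93, 34.4-fold), and GZMA, which encodes the granule protease granzyme A (5.10 ± 1.67, 34.3-fold). FASLG, the ligand of the death receptor FAS, was 11.7-fold higher (3.55 ± 0.23), and EOMES, a transcription factor of cytotoxic and memory T cells, rose by 3.28 ± 0.34. LMCD1 (3.63 ± 0.59), GZMK, another granzyme (3.43 ± 0.59), and SOCS3, an inhibitor of cytokine signalling (3.38 ± 1.00), rose as well. FSTL5 rose by 3.56 ± 0.28 but was not above background in any empty-vector clone, so that its size depended on the background correction, with 7.73 from the scanner software's processed signals. The largest decreases were in GSTP1, a glutathione transferase (-5.11 ± 0.74, 34.5-fold lower), GNLY, which encodes the cytolytic protein granulysin (-4.10 ± 0.49), and MAL, a membrane protein of T cells (-3.81 ± 0.32). KLRC4 (-3.26 ± 0.88) and KLRC3 (-2.39 ± 0.05), related genes of the NKG2 receptor family, fell, as did the heat shock gene HSPA1A (-3.18 ± 1.00), the focal adhesion gene PXN (-3.02 ± 0.36) and the transcription factor KLF2 (-2.61 ± 0.53). FGR (-2.52 ± 0.46), ATP8B4 (-2.44 ± 0.38), GEM (-3.11 ± 0.83) and VSIG1 (-2.61 ± 0.57) completed the 12 lowest, the last 2 above background in red on 1 array. Shared signal between the probes of KLRC3 and KLRC4, or of HSPA1A and its near-identical paralog, was not measured.

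Across all genes, 1865 of 20144 genes and unnamed transcripts were higher in the SATB1 clones and 1559 were lower at an adjusted p under 0.05 (limma). Of these, 272 of the higher and 154 of the lower ones were changed at least 2-fold, and 61.9% of all calls were under 1.5-fold. A change of over 2-fold on every array, counted without a test, was seen for 170 genes upward and 79 downward. The sign of the ratio was the same on all 3 arrays for 58.1% of the genes, against 25% if signs were even and independent between arrays. A dye bias of single genes would also repeat a sign, as the dyes were not swapped. Of the 7 spike-in controls (added transcripts) above background in both channels, 4 had the same sign on all 3 arrays. The number of calls depended on the replicates: 182 genes were higher and 90 lower without replicate 1, 260 and 124 without replicate 2, and 2065 and 1555 without replicate 3. With the 2 channels of an array treated as unpaired samples, 706 genes were higher and 476 lower.

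Directions are relative to the typical gene of each array, because the median of all genes moved to 0.40 with median centring and to 2.00 with no within-array normalization. The genes higher and lower then numbered 11729 and 1405, and 20059 and 18. Many named genes with smaller decreases had positive ratios in those settings, each below the shifted median. Of the 24 genes with the largest increases and decreases, 22 were still called without replicate 1, 19 without replicate 2 and 24 without replicate 3. GEM lost its call without replicate 1, and GZMA, SOCS3, KLRC4 and HSPA1A lost theirs without replicate 2. GZMA had ratios of 3.95, 4.34 and 7.01, with a mean of 4.14 without replicate 3. SLA, an adaptor of T cell receptor signalling (3.59 ± 2.23), was called neither without replicate 1 nor without replicate 2, its ratios were 1.57, 3.22 and 5.97, and it was above background in green on 2 arrays only. Another probe of SLA gave 0.50, and other probes also gave smaller ratios for SOCS3 (0.48), KLF2 (-0.54), FGR (-1.28 and -0.70), HSPA1A (-1.46 and -1.59) and FASLG (2.64).

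**Figure D1:**
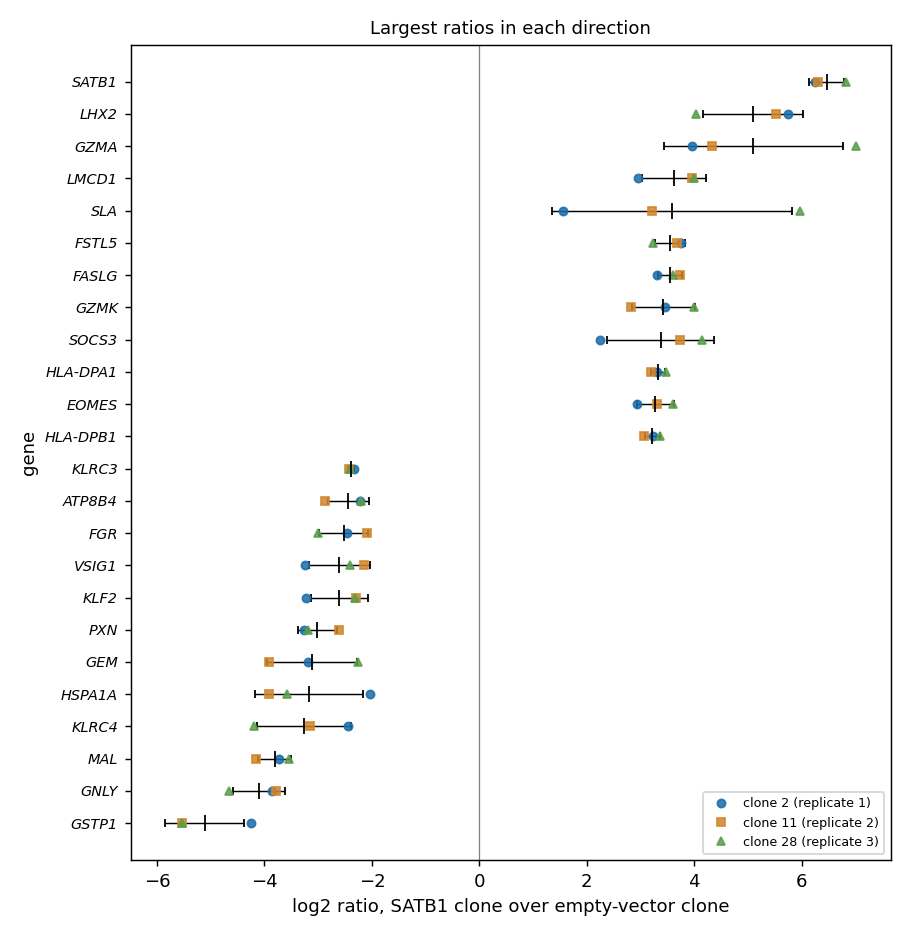
Log2 ratio of the SATB1 clone over the empty-vector clone (x axis) for the 12 genes with the largest increases and the 12 with the largest decreases (y axis), by the rule fixed in advance. Coloured points are the 3 arrays, black ticks the mean and black bars the SD (n = 3); SATB1 sits at 6.47 and GSTP1 at -5.11.

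MHC class II genes, which present antigen to CD4 T cells, rose together. HLA-DPA1 rose by 3.32 ± 0.14 (10.0-fold), HLA-DPB1 by 3.22 ± 0.14 (9.33-fold) and HLA-DQB1 by 2.49 ± 0.10 (5.61-fold). CIITA, the master regulator of class II transcription (1.76 ± 0.44), and CD74, the invariant chain (1.49 ± 0.11), also rose, as did CTSS, the protease that trims the invariant chain (0.46 ± 0.21). These 3 genes are unrelated in sequence to the HLA genes and were named because a test of cross-hybridisation used them. Of 14 list members measured, 13 rose and 0 fell, 13 and 0 when adjusted over the list alone. The remaining member, HLA-DOB, had a ratio of -0.14 ± 0.17. The median of the list was 1.98 (camera adjusted p = 3.24e-13; adjusted p = 0.533 with an estimated correlation). Without replicate 1 and without replicate 2, 11 of the 13 were still called, CTSS not among them. In the same clones the 8 measured B cell markers had a median of 0.20.

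Genes of cell death changed singly. In the death receptor list, FASLG and TNFRSF1A, a receptor of TNF (0.45 ± 0.03), rose and TNFRSF25, another death receptor (-0.87 ± 0.20), fell, which makes 2 up and 1 down of 20 measured, or 3 and 2 adjusted over the list alone. BBC3 (-0.58 ± 0.26) and BAX (-0.43 ± 0.15), which promote apoptosis, fell among 12 pro-death members of the BCL2 family, with 1 up and 2 down adjusted over the list alone. Both had positive ratios with median centring (0.26 and 0.17) and without normalization. None of 11 survival genes passed the limma test, and 3 had an unadjusted p under 0.05. Without replicate 1 and without replicate 2, FASLG was the 1 call left of the 3 death receptor calls, and BBC3 and BAX both lost theirs. BAX was not called without replicate 3 either, and neither was called without the replicate block. The camera test placed none of the 3 lists apart from other genes (adjusted p = 0.959, 0.892 and 0.858).

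Genes of T helper and cytotoxic programs moved in both directions. EOMES, the interferon gamma receptor chain IFNGR1 (1.08 ± 0.06) and IFNG, named after its values were seen (1.46 ± 0.21), rose, while the chemokine CCL5 fell by 1.27 on the log2 scale. Of 17 Th1 genes measured, 6 rose and 2 fell, 6 and 3 adjusted over the list alone. In the Th2 list IL10 rose (1.88 ± 0.36) and CCR8 fell (-0.90 ± 0.38), as did IL13 (-0.64 ± 0.09, above background in red on 1 array), with 2 up and 2 down of 14 by both adjustments. TNFRSF18, the costimulatory receptor GITR (-2.29 ± 0.58), and TGFB1 (-0.96 ± 0.49) fell and the transcription factor RORA (0.67 ± 0.24) rose in the Th17 and regulatory T cell list, with 1 up and 4 down of 11 by both adjustments. In the cytotoxic list GZMA and GZMK rose and GNLY fell, with 4 up and 3 down of 16, or 6 and 6 adjusted over the list alone. The camera adjusted p of these 4 lists lay between 0.534 and 0.959, but the Th17 and regulatory T cell list passed with median centring (median -0.24, adjusted p = 0.00146) and with no normalization (median 1.36, adjusted p = 8.89e-09). Both medians lay below the shifted median of all genes, and the highest adjusted p was 0.686 over the preset-correlation alternatives. With no normalization the cytotoxic list passed camera downward (adjusted p = 1.22e-08, up to 0.997 over these alternatives). So did the Th2 list (adjusted p = 0.0274, up to 0.994). The cytotoxic median (2.20) nevertheless lay above the shifted median of all genes. By fry the Th1 list passed upward (adjusted p = 0.0271). Without normalization the ratios of CCL5, CCR8, IL13 and TGFB1 were positive. Without replicate 1 and without replicate 2, 4 of the 8 Th1 calls (EOMES, IFNGR1, IFNG and CCL5) and 1 of the 5 Th17 calls (TNFRSF18) were left, so that RORA and TGFB1 lost theirs. Of the 4 Th2 calls IL10 was left without replicate 1 and IL10 and CCR8 without replicate 2, and of the 7 cytotoxic calls GZMA, GZMK and GNLY without replicate 1 and GZMK and GNLY without replicate 2.

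Homing, checkpoint and T cell receptor genes moved in both directions. KLF2, CCR1, a chemokine receptor (1.93 ± 0.43), and CXCR5, the follicular homing receptor (1.45 ± 0.24, above background in green on 1 array), had the smallest p among homing genes, and SELPLG, the selectin ligand PSGL-1, fell (-0.76 ± 0.06). Of 18 homing genes 5 rose and 9 fell, 6 and 9 adjusted over the list alone, at a median of -0.32 (camera adjusted p = 0.593). Without replicate 1 and without replicate 2, 3 of these 14 calls were left. Among checkpoint genes the inhibitory receptor LAG3 (2.12 ± 0.46) and the costimulatory receptor TNFRSF9 (1.24 ± 0.05) rose, and TNFSF14 (-0.44 ± 0.19) fell but was positive (0.06) with median centring. Of 9 checkpoint genes 2 rose and 2 fell, 2 and 3 adjusted over the list alone. In T cell receptor signalling CD5 (-0.68 ± 0.19) fell and the kinase FYN (0.44 ± 0.07) and TRAT1 (0.45 ± 0.12) rose, with 3 up and 4 down of 26, or 3 and 5 adjusted over the list alone. Without replicate 1 and without replicate 2, 0 of these 7 calls and 2 of the 4 checkpoint calls were left. The camera adjusted p was 0.959 for checkpoint genes, which passed fry upward (adjusted p = 0.0485), and 0.858 for T cell receptor signalling. The homing list passed camera with no normalization (adjusted p = 0.00595, up to 0.901 over the preset-correlation alternatives).

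Ribosomal protein genes were shifted upward by small amounts: 12 of 37 rose and 0 fell, 20 and 0 adjusted over the list alone, at a median of 0.33. RPL7A (1.05 ± 0.11), RPL26 (0.58 ± 0.08) and RPL5 (0.56 ± 0.08) rose. Random lists of the same brightness had a median of 0.11. Such lists were drawn only for the 3 lists that passed camera. Of the 12 called genes, 9 were larger in size than the most extreme ratio of the spike-in controls, 0.38 in size. The brightest of these controls was also higher in red on all 3 arrays, at a mean of 0.22. The list median was 0.16 with the scanner software's processed signals and with the authors' table, which hold the same ratios. There the list still passed camera (adjusted p = 0.0057). Over the preset-correlation alternatives its camera adjusted p lay between 5.52e-08 and 0.0057. The list passed camera (adjusted p = 5.18e-06; adjusted p = 0.533 with an estimated correlation). Cholesterol synthesis genes gave 6 up and 2 down of 20, 9 and 2 adjusted over the list alone, at a median of 0.26. The sterol enzymes MSMO1 (0.89 ± 0.20) and HMGCS1 (0.78 ± 0.26) rose and MVK, mevalonate kinase, fell (-0.42 ± 0.05). The cholesterol list passed camera (adjusted p = 0.0107; adjusted p = 0.975 with an estimated correlation and 0.156 by fry), but not without replicate 1 (adjusted p = 0.0619) or without replicate 3 (adjusted p = 0.0616), and over the alternatives with the preset correlation its adjusted p lay between 0.00108 and 0.0619. Single calls were fewer too: without replicate 1, 0 of the 12 ribosomal and 0 of the 8 cholesterol calls were left, and without replicate 2 RPL7A, HMGCS1 and MSMO1 were left.

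Among stress and cell cycle genes some rose and others fell. JUN, an immediate early transcription factor (1.08 ± 0.17), rose and the heat shock genes HSPA1A and HSPB1 (-1.53 ± 0.43) fell, giving 3 up and 2 down of 20 heat shock and early response genes by both adjustments. HSP90B1 (0.62 ± 0.10) and DNAJB9 (0.64 ± 0.11), chaperones of the endoplasmic reticulum, rose, with 3 up and 1 down of 19, or 7 and 2 adjusted over the list alone. TOP2A (0.47 ± 0.09) and TTK (0.49 ± 0.11) rose among 29 mitotic genes, of which 5 rose and 1 fell by both adjustments, at a median of 0.082. The mitotic list passed camera with median centring (median 0.68, adjusted p = 0.00146) and with no normalization (median 2.28, adjusted p = 0.0065), and its adjusted p went up to 0.828 over the preset-correlation alternatives. The replication list passed camera upward with median centring (adjusted p = 0.0189, up to 0.937). The heat shock list passed camera downward with no normalization (adjusted p = 0.000145, up to 0.996), although its median (2.39) lay above the shifted median of all genes. MCM2 (-0.46 ± 0.03), a replication factor, fell with 3 others of 30 replication genes while 1 rose, by both adjustments, and MCM2 was positive (0.24) with median centring. Among p53 targets TP53INP1 (0.85 ± 0.34) and CCNG1 (0.55 ± 0.18) rose, with 3 up and 2 down of 20, or 4 and 5 adjusted over the list alone. The camera adjusted p of these 5 lists lay between 0.593 and 0.892. Of the 5 heat shock and early response calls, HSPA1A, HSPB1 and JUN were left without replicate 1 and JUN alone without replicate 2, and 0 calls were left in the other 4 lists in either case.

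Inflammatory, antigen presentation and reported SATB1 target genes also moved both ways. The cytokine CSF2 (-1.70 ± 0.55, above background in red on 2 arrays) fell and TRAF1 (0.56 ± 0.19) and ICAM1 (0.66 ± 0.34) rose among 17 NF-kB targets, with 3 up and 1 down by both adjustments. IFITM3 (-0.78 ± 0.17) fell and RSAD2 (0.79 ± 0.24) rose among 27 interferon-stimulated genes, with 3 up and 3 down, or 6 and 4 adjusted over the list alone. In the MHC class I list CANX (0.63 ± 0.16) and ERAP2 (0.54 ± 0.09) rose, with 2 up and 3 down of 21, or 3 and 4 adjusted over the list alone. TWIST1 (0.83 ± 0.09), a gene reported in Sezary cells, rose, and that list had 5 up, SATB1 among them, and 2 down of 20, or 5 and 5 adjusted over the list alone. VIM (0.64 ± 0.16) rose and S100A4 (-1.16 ± 0.55) fell in a list of genes reported with SATB1 in breast cancer, with 3 up and 3 down of 14, or 4 and 4 adjusted over the list alone. ADM (0.93 ± 0.20), which encodes adrenomedullin, rose among hypoxia genes, with 2 up and 1 down of 23, or 4 and 3 adjusted over the list alone. EP300 (0.48 ± 0.03, down to 0.28 over the alternatives), an acetyltransferase, rose in the list of chromatin partners. That list had 2 up and 0 down of 17, or 1 and 0 adjusted over the list alone. The camera adjusted p of these lists lay between 0.593 and 0.959. With median centring the MHC class I list passed camera upward (adjusted p = 0.0223, up to 0.994 over the preset-correlation alternatives). So did the chromatin partners (0.0455, up to 0.996). The breast cancer list passed camera downward with no normalization (adjusted p = 0.00595, up to 0.994), although its median (2.21) lay above the shifted median of all genes. The interferon list passed by fry, upward (adjusted p = 0.0425). Without replicate 1 the calls left were CSF2 and SATB1, and without replicate 2 ADM and SATB1.

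Markers of other cell types were mixed. PECAM1, an adhesion molecule of endothelium and of some T cells, rose by 3.00 ± 0.63, PDGFRB by 2.77 ± 1.55, and EPCAM fell (-0.60 ± 0.15; 0.10 with median centring), giving 2 up and 1 down of 7 stromal and epithelial markers, or 3 and 1 adjusted over the list alone. CD79A (0.46 ± 0.04) and CD79B (0.76 ± 0.26) were the 2 that rose among 8 B cell markers, with 3 up and 0 down adjusted over the list alone. CSF1R rose (0.80 ± 0.09) and FCER1G fell (-0.37 ± 0.12; 0.20 with median centring) among 5 myeloid markers, by both adjustments. PDGFRB and CSF1R were not above background in any empty-vector clone, with 6.20 and 2.93 from the scanner software's processed signals. PDGFRB had ratios of 1.76, 1.99 and 4.55, with a mean of 1.87 without replicate 3, and was not called without replicate 1 or without replicate 2, and CSF1R was not called without replicate 1. TFRC, the transferrin receptor (0.65 ± 0.07), rose among 4 erythroid markers and none of 4 globin genes passed the limma test, with 0 at an unadjusted p under 0.05. Without replicate 1, the call left in these lists was PECAM1, and without replicate 2 PECAM1 and CSF1R were left. The camera adjusted p was 0.858 for stromal and for myeloid markers and 0.470 for B cell markers, and the myeloid list passed with no normalization (adjusted p = 0.00898, up to 0.994 over the preset-correlation alternatives).

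**Figure D2:**
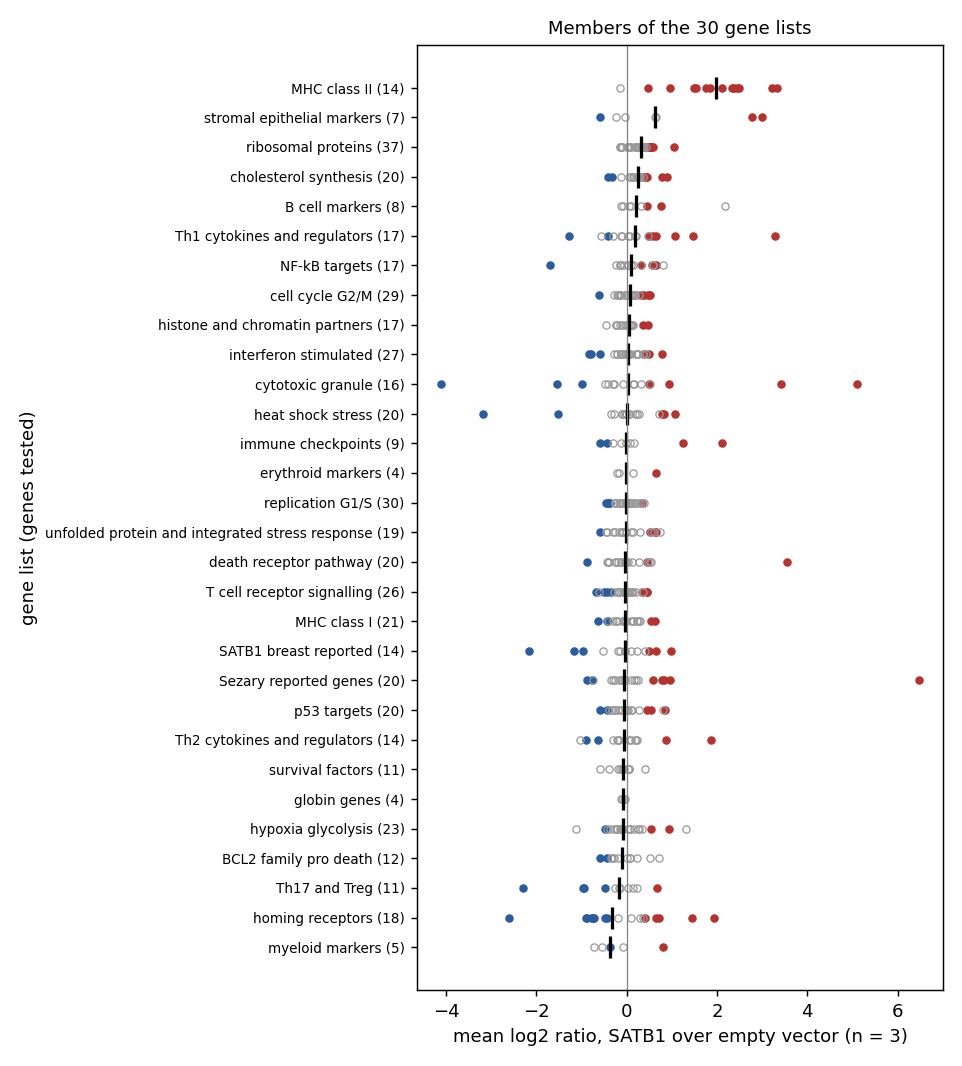
Mean log2 ratio of the 3 arrays (x axis) for each measured member of the 30 gene lists (y axis, number of genes measured in brackets), sorted by the list median, which is the black bar. Filled red points rose and filled blue points fell at an adjusted p under 0.05, and open points did not pass; the median is 1.98 for MHC class II and 0.33 for ribosomal proteins.

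The 3 pairs of clones changed alike to different degrees. Across genes, which are not independent replicates, the ratios of replicates 1 and 2 had a Pearson r of 0.82 (Spearman rho 0.71), those of replicates 1 and 3 an r of 0.69 (rho 0.62) and those of replicates 2 and 3 an r of 0.63 (rho 0.50). Among SATB1 clones, 65 genes were over 2-fold apart between replicates 1 and 2, 655 between 1 and 3 and 604 between 2 and 3. Among empty-vector clones these numbers were 19, 358 and 437. Each count compares 1 channel between 2 arrays, so that it also carries what the arrays add. Across genes, the differences of the 2 channels had an r of 0.25 for replicates 1 and 2, 0.57 for 1 and 3 and 0.49 for 2 and 3.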

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

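The tests of whole-transcript dye bias, of class II-bearing cells and of chromosome segments that differ between the groups were chosen only after the results were seen, and the bounds for the share of the ratio left were set after related values were seen.

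Spike-in controls, added transcripts that no comparison used and whose mixture in each dye is not given in the sources used here, gave ratios above background in data outside the main measurement. The mean log2 ratio that was largest in absolute size among the 7 controls above background in both channels was -0.38. The slope of observed on expected log ratios in the file headers was 0.0214 on array 1, -0.0114 on array 2 and 0.0425 on array 3, and what was expected rests on mixtures that are not known here.

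The first pattern weighed is the 3424 genes that differed between SATB1 and empty-vector clones. Turning the sign of 1 array at a time called 0 genes at most against 3424 for the real orientation, the 1 of 4 that reached that count, and 4 orientations are too few for a share under 0.05; at an unadjusted p under 0.05 the turned arrays gave 36 to 359 genes. Faults of single probes were argued against by the other probes of 739 called genes, which carried a median of 0.64 of the change (95% bootstrap interval 0.59 to 0.68). Broad segments as the source of most of the ratio were argued against by the share left relative to the running median of 25 neighbouring genes. The median of that share was 0.87 (0.86 to 0.89). A running median misses short segments, the interval treats neighbouring genes as independent, and the share left with genes in random order was not measured. Calls that stayed were 62.1% of the 2173 made when the 10389 genes with enough neighbours were fitted and adjusted by themselves, against 77.5% to 83.5% with genes in random order. In the 824 that ended, the median absolute log2 ratio shrank from 0.42 to 0.26 with the standard error at 0.080 before and after. Choosing calls that ended favours a smaller ratio, and in 585 of the 824 at least as much of the ratio was left as was lost. For these 824 calls segments and SATB1 cannot be told apart. Dye bias of whole transcripts cannot be told apart from SATB1 either, since every SATB1 clone was red: 16.4% of the calls were no larger in size than the most extreme spike-in ratio, and the added SATB1 remains an open biological explanation.

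The next pattern is the rise of MHC class II genes. Cross-hybridisation among related HLA probes as the only source of the rise was argued against by CD74, CIITA and CTSS, of other sequence, at a median of 1.49, with the smallest ratio in CTSS. Signal shared between single HLA probes was not measured. B or myeloid cells among the clones would bring their abundant transcripts, yet the 8 B cell and 5 myeloid markers measured had a median of 0.061 (upper 95% bootstrap bound 0.46) against 1.98 for class II, and only 8 of 13 B cell and 5 of 15 myeloid markers on the array were above background in every SATB1 clone. These markers moved in both directions, with 2 B cell and 1 myeloid marker called higher and 1 myeloid marker called lower. Dye bias has no swap to exclude it, though all 13 called class II genes lay beyond the spike-in ratios. Other probes gave 2.90 for HLA-DPA1 and 3.01 for HLA-DPB1. With the mean over the probes of a gene, the list median was smaller, 1.66 against 1.98. Regulation by SATB1 through CIITA is a hypothesis that these data did not test.

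The last pattern is that clones moved apart from each other, with 231 genes over 2-fold apart in replicate 3 from both other arrays, against 31 and 42 for replicates 1 and 2. Gains or losses of chromosome segments in single clones may contribute: the deviation of an array from the others was correlated between neighbouring genes at up to 0.19, against 0.032 at most in 1000 shuffled orders. Added SATB1 acting on whole regions would give this in the SATB1 channel alone, but the neighbour correlation was 0.10 to 0.11 there and 0.082 to 0.13 in the empty-vector channel, which argues against it as the only source. Both channels also carry what the array adds, and how far that bears on neighbouring genes was not tested.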

How the results depend on the processing

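SATB1 kept its direction and its adjusted p under 0.05 in all alternatives run, with log2 ratios from 6.28 to 8.69 and adjusted p from 3.21e-06 to 0.00981. Of the named genes over all alternatives, 1585 values stayed on their side of the threshold. These include values that changed sign while called in neither setting, and 110 from leaving out saturated probes, which repeats the main run. In the same direction, 215 lost their call and 14 gained one, and 47 changed sign while called before or after. The scanner software's processed signals and the authors' table hold the same ratios. Their 92 unchanged values and 18 lost calls are therefore counted for each of them. Calls depended on which replicate was left out and on normalization. Leaving out 1 replicate gave 182 to 2065 genes higher, 90 to 1555 lower, 309 to 358 changed at least 2-fold on every array left and 2 to 3 lists. The number of calls fell without replicate 1 or 2 and not without replicate 3. Replicates 1 and 2, left in the last case, were the most alike pair (Pearson r 0.82). The pairs left without replicate 1 and without replicate 2 had an r of 0.63 and 0.69. The many calls thus go with the agreement of replicates 1 and 2, and no other cause was tested. Without the replicate block, so that the pairing of each SATB1 clone with its own empty-vector clone was dropped, 706 genes were higher and 476 lower, all 1182 of them among the calls with the block. The scanner software's processed signals and the authors' table, being the same ratios, both gave 1109 genes higher, with 514 changed at least 2-fold on every array. They are not independent of each other, and the cause of the difference from the main run was not tested. An adjusted p under 0.01 left 210 higher and 109 lower, a further limit of 2-fold left 272 and 154, and 708 genes changed at least 1.5-fold on every array. For lists, camera with an estimated correlation passed 0 (2 at an unadjusted p under 0.05) and fry, which asks another question, passed 5: MHC class II, ribosomal, Th1, checkpoint and interferon, not cholesterol. Median centring, which leaves the trend with brightness in place, gave 11729 genes higher, 660 changed at least 2-fold on every array and 8 lists, with Th17 and regulatory T cell genes (median -0.24), mitotic genes (0.68), chromatin partners (0.67), MHC class I (0.68) and replication (0.60) newly past the threshold. Genes that turned positive there lay below the shifted median of all genes, 0.40: BBC3 0.26, BAX 0.17, BAG1 0.34, TNFSF14 0.061, PTTG1 0.099, MCM2 0.24, E2F1 0.21, HERPUD1 0.11, ALDOA 0.24, FCER1G 0.20, EPCAM 0.10 and HLA-DOB 0.30. By camera the MHC class I and replication lists turned from down to up, with medians above the shifted median. No within-array normalization, which leaves the brighter red dye in every ratio, gave 20059 genes higher, 18 lower, 19162 changed at least 2-fold on every array and 11 lists, with the Th2 (1.72), Th17 (1.36), homing (1.91), breast cancer (2.21), mitotic (2.28), myeloid (1.63), cytotoxic (2.20) and heat shock (2.39) lists newly past the threshold. Genes that turned positive there lay below the shifted median, 2.00: TNFRSF25 1.37, BBC3 1.86, BAX 1.77, BAG1 1.94, BCL2L1 1.65, IL13 0.61, CCR8 1.17, CCL5 0.94, TGFB1 1.17, CD5 1.44, TNFSF14 1.66, IFITM3 1.51, IFI6 1.19, SELPLG 1.41, S100A4 1.22, HBQ1 1.41, HBA1 1.32, HBM 1.44, PTTG1 1.70, MCM2 1.84, E2F1 1.81, HSPB1 0.66, HERPUD1 1.71, ALDOA 1.84, MVK 1.504, CTBP1 1.81, FCER1G 1.79, TYROBP 1.31, EPCAM 1.70, EPOR 1.48, SLC4A1 1.65, HLA-DOB 1.90, PRF1 1.20, ITGB1 1.31 and ITGA4 1.09. By camera the cytotoxic and heat shock lists turned from up to down, although their medians lay above the shifted median. The breast cancer list also passed downward with a median above the shifted one. Leaving out saturated probes removed no probe. Low signal over background limits genes such as FSTL5 and CSF1R, which were not above background in green on any array, to ratios that depend on the background correction.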

Other observations

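The runs of neighbouring genes and the genes named in this part were chosen only after their values were seen.

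Replicate 3 parted from the others in single genes. MET, a growth factor receptor, was lower in the SATB1 clones of replicates 1 and 2 (-2.21 and -2.01) and higher in replicate 3 (2.39), and FUCA2, a fucosidase, went the opposite way (2.09, 2.27 and -1.97). The integrin genes ITGB1 (-0.88 ± 0.15, SD, n = 3) and ITGA4 (-0.90 ± 0.20) fell in all 3 pairs, as did PRF1, which encodes perforin (-0.98 ± 0.46). None of these last genes was called without replicate 1 or without replicate 2. Of the 231 genes apart in replicate 3, 171 differed more in the SATB1 channel than in the empty-vector channel.

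Neighbouring genes shifted together in a few places. On chromosome 8, all 35 genes from GSDMD to PPP1R16A were lower in the SATB1 clones, 28 of them called, at a median of -0.63 (-0.64, -0.61 and -0.61 on the 3 arrays). On chromosome 2, all 23 genes from MRPS5 to MGAT4A were lower (-0.49), and on chromosome 9, 10 of 11 genes from JAK2 to ZDHHC21 (0.66) and 13 of 15 from PPP3R2 to PTPN3 (0.53) were higher. The 100 genes in such runs held 73 of the 2019 calls that 10389 genes with enough neighbours had when adjusted with all 20144. Other runs belonged to 1 clone: 49 of 50 genes from SLC25A16 to AP3M1 on chromosome 10 were lower in empty-vector replicate 2 than in the others (-0.47) and all 20 from IDUA to TNIP2 on chromosome 4 were lower in SATB1 clone 11 (-0.37). Genes around the class II locus that are not on its list had a median of -0.12 (36 genes). Over all 10918 pairs of neighbouring genes, inside and outside runs, the correlation of the mean ratio was 0.18, against 0.037 at most in shuffled orders, and that of the deviation of single arrays was up to 0.19. Copy number differences between clones may underlie these runs, but DNA was not measured.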
